A study of Homo sapiens with 3 samples.

How the data were processed

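The series measured sorted KIR+ CD8 T cells of donors in pregnancy and after delivery in 3 pools, on a targeted BD Rhapsody panel with sample tags, with the TCR of the same cells. Per the file headers, the deposited expression tables hold whole-number molecule counts per gene and cell, and the deposited TCR tables hold molecule counts of the dominant chain per cell, its V gene and CDR3, and a cell type call per cell. The aligner, the molecule correction, the genome build and the caller of cell types are not given in the sources used here, so no coordinates are printed. Seurat 3.0 is named in the submitters' processing notes. Each cell's sample tag call was deposited, and the tag table gives a donor code and a stage for each tag. The tag calls covered 17027 cells, of which 1383 were multiplets (12.5% of pool 3, 2.57% of pool 2 and 1.97% of pool 1) and 86 undetermined; the matrices hold single-tag cells only. No further doublet caller was run, and the 24 cells above 3 times their specimen's median were left out as an alternative. Donors are not named, and no donor-level sequence or genotype is printed.

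Stages came from the tag table alone. It names the second trimester, the third trimester and 2 postpartum windows, which were joined, and it names no diagnosis group, so that comparison was not made. Specimens with at least 20 cells were kept (5 were dropped), and specimens of a donor and stage were summed, including 5 labels run in 2 pools. Donors are separate people. In comparisons paired or blocked by donor, p-values measure the spread of the differences within donors. The comparisons of the second trimester with postpartum and between the trimesters had no donor block. There, the 25 sums of 17 donors counted as independent, although some donors entered more than once. The pairing of specimens comes from the donor codes.

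Summed counts were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. All stages entered one fit. Where at least 3 donors had both sides of a contrast, the donor was a block (pregnancy or the third trimester against postpartum); otherwise the share of molecules from each pool was a covariate. CPM values are TMM-scaled, and standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. For 22 of 319 genes in pregnancy against postpartum (LAG3, NCR1 and KLRF1 among them), and 15, 7 and 20 in the third trimester against postpartum, the second trimester against postpartum and between the trimesters, edgeR's Poisson bound raised the p-value, so that it is larger than the fold change and its standard error give. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where 3 or more members were tested, against the tested panel genes; estimated correlations and fry were alternatives. The lists were regulatory, NK receptor, cytotoxic, naive and memory, terminal effector, checkpoint, activation, immediate early, interferon response, cytokine, homing and cytokine receptor genes and markers of NK, B and myeloid cells. KIR (KIR2DL1), proliferation, CD4 and gamma-delta lists had too few tested members. DESeq2 1.42.0 was an alternative.

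The genes named in each comparison were set before the data were examined: up to 12 risen and 12 fallen genes past the threshold by fold change, the 6 with the smallest p where fewer than 10 passed, and, for pregnancy against postpartum, every tested KIR, regulatory and NK receptor gene. Other members of the interferon list were named after their values were seen. For a gene that did not pass, a change of direction under an alternative was counted only where the value moved by more than 1 SE.

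A clone was the V gene and CDR3 nucleotide sequence of the beta chain within a specimen. Expansion was the share of 30 drawn cells in clones of 2 or more cells (mean of 200 draws) in specimens with at least 30 such cells. Differences were tested by exact two-sided sign changes within donors, or by permutation over donors (exact, or 100000 resamples). The permutation took the pregnancy and postpartum means of a donor as independent, although 6 donors had both (5 for clones). Cells were clustered on log counts scaled to the median total and centred within pool, with 20 principal components, an exact graph of 15 neighbours and Leiden at resolution 0.6 (leidenalg 0.10.2, igraph 0.11.9). Names required markers fixed before the data were examined. Shares of cells with a molecule were also computed after thinning each cell to 150 molecules, which leaves out 157 pregnancy and 1 postpartum cells.

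Precision follows depth: pool 1 held 1021065 molecules, pool 2 3061579 and pool 3 7406845. On simulated counts drawn from the means, totals and dispersions of the pregnancy against postpartum fit, with 200 of 319 genes changed, edgeR recovered 58.0% of genes changed 1.5-fold, 78.0% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and called 1.68% of unchanged genes. For the third trimester against postpartum it recovered 42.0%, 82.0%, 98.0% and 100%, in the same order. It recovered 30.0%, 46.0%, 90.0% and 92.0% for the second trimester against postpartum and 38.0%, 56.0%, 90.0% and 98.0% between the trimesters. The simulation held no donor differences, so these shares say nothing of differences that donors add. It also changed 200 of 319 genes, which eases the Benjamini-Hochberg cut. Recovery in the data, where few genes passed, may therefore be lower than these shares. Expanded clones (3 cells or more) were compared with clones of a single cell in edgeR, with each donor and stage as a block, a contrast added after the data were seen. Alternatives covered the block, the pool covariate, normalization, filters, cell selection, pools and donors left out.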

Results

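KIR+ CD8 T cells are a subset of CD8 T cells that carry killer-cell immunoglobulin-like receptors, inhibitory or activating receptors best known from natural killer (NK) cells. The series profiled such cells, sorted from donors sampled during pregnancy and after delivery, with a targeted single-cell gene panel and with T cell receptor (TCR) sequences of the same cells. Specimens were marked with sample tags and run in 3 pools of 12 tags each. The matrices held 15504 cells with a single tag, 3473 in pool 1, 3581 in pool 2 and 8450 in pool 3. Of the 36 tagged specimens, 31 had at least 20 cells and entered the expression comparisons. They came from 17 donors and made 25 donor-by-stage sums, 6 from the second trimester, 12 from the third trimester and 7 postpartum. Postpartum specimens were drawn under 90 days (3 donors) or over 180 days (5 donors) after delivery. A total of 6 donors had both a pregnancy and a postpartum specimen, 5 of them in the third trimester and 1 in the second. Cells per specimen ranged from 25 to 2685, and molecules per specimen from 6899 to 2531703. The median cell held 283 molecules in pool 1, 783 in pool 2 and 816 in pool 3. Pool 1 held no postpartum specimen.

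The sort was almost entirely T cells of the CD8 lineage. The deposited annotation called 54.9% of cells memory CD8 T cells (Wilson 95% interval 54.1% to 55.7%) and 42.3% naive CD8 T cells (41.5% to 43.0%). The clustering below did not bear out so large a naive share. Its only naive or central memory CD8-like cluster held 11.6% of cells, and outside it CCR7 was seen in 4.95% of cells and SELL in 13.5%. CD4 memory T cells made up 1.25%, CD4 naive T cells 0.709%, NK cells 0.626%, gamma-delta T cells 0.0967%, classical monocytes 0.0645% (10 cells), B cells 0.0451% (7 cells) and nonclassical monocytes 0.0129% (2 cells). These intervals cover counting error only. In the 6 donors with both sides, the NK share was 1.59% in pregnancy and 0.257% postpartum, higher in 5, which did not separate from 0 in an exact two-sided sign-change test (p = 0.219) or over all donors in a permutation test (p = 0.0521). That permutation took both sides of these 6 donors as independent. CD8A, a chain of the CD8 coreceptor, had a molecule in 98.4% of cells, CD8B in 80.0% and CD3E in 95.5%. KIR2DL1, the KIR gene on the panel, was seen in 45.0% of cells, and IKZF2, which encodes the regulatory transcription factor Helios, in 39.4%. TYROBP, an adaptor of activating NK receptors, was seen in 47.0% of CD8-annotated cells with a beta chain (median 710 molecules) and in 51.6% of cells without an alpha or beta chain (median 665.5). The corresponding shares were 47.6% and 50.1% for the NK receptor gene KLRF1, and 1.00% and 1.15% for NCAM1. Thinned to 150 molecules per cell, the TYROBP shares were 23.5% and 26.6%. CD14, a monocyte receptor, was seen in 1.15% of cells, CD4 in 2.20% and the B cell gene CD79A in 0.909%. The share of cells without an alpha or beta chain was 1.59 percentage points higher in pregnancy than postpartum in the 6 donors with both (SD of the differences 10.1, 4 of 6 donors higher), which an exact two-sided sign-change test did not separate from 0 (p = 0.688). The direction turned without pool 3 (−2.43 points, 3 donors) and in one of the fits with a donor left out (−1.42 points).

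The first comparison asked how expression in pregnancy, taken as the mean of both trimesters, differed from that postpartum, with the donor as a block. The second trimester had the same weight as the third, though only 1 donor had it with postpartum and 2 donors had both trimesters. The fitted fold changes are therefore not averages over the 6 paired donors. KIR2DL1, the KIR gene on the panel, had a log2 fold change of 0.07 ± 0.17 (SE), with 1442 ± 1022 CPM in pregnancy (SD, n = 18 donor-by-stage sums) and 1487 ± 686 postpartum (n = 7). IKZF2 had −0.11 ± 0.14 and was lower in 5 of 6 paired donors, and TIGIT, an inhibitory checkpoint receptor, had 0.11 ± 0.14. None of 319 tested genes passed the threshold in edgeR (22 at an unadjusted p under 0.05, lowest adjusted p = 0.387), and DESeq2 called 4.

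Of the 7 tested regulatory genes, none passed. TGFB1, an immunosuppressive cytokine, had 0.52 ± 0.27, but −0.10 with the pool covariate added and −0.032 with donor and pool as one block, and was 1.98 log2 units higher in pool 1 in 5 of 5 specimen labels run in another pool too. LAG3 had −0.31 ± 0.18, ENTPD1 0.41 ± 0.60, FOXP3 0.22 ± 0.83 and CTLA4 −0.04 ± 0.43. Of the 15 tested NK receptor genes, none passed either, and 6 had a positive and 9 a negative value. The adaptor TYROBP had 0.46 ± 0.20 and was higher in 5 of 6 paired donors, CD226 −0.86 ± 0.40, CD160 1.32 ± 0.82, CD244 0.36 ± 0.26, NCR3 0.32 ± 0.28 and NCR1 0.25 ± 0.34. Among genes of the NKG2 family, KLRC1 was at −0.05 ± 0.16, KLRC2 at −0.06 ± 0.15, KLRC3 at −0.19 ± 0.14, KLRC4 at −0.29 ± 0.18 and KLRK1 at −0.12 ± 0.10. KLRC1 was lower in 6 of 6 paired donors. KLRB1 had −0.25 ± 0.29, KLRG1 −0.19 ± 0.23, KLRF1 0.12 ± 0.18 and the Fc receptor FCGR3A −0.08 ± 0.27. The fold changes of IKZF2 and KLRC3 had the opposite sign without pool 1, at 0.077 and 0.089. With the pool as a covariate in place of the donor block, KLRC1 was at 0.42, KLRC2 at 0.39, KLRC4 at 0.041, KLRF1 at −0.27, CD160 at −0.35 and CTLA4 at 0.90, again without passing, and with it added to the donor block ENTPD1 was at −0.68. Without pool 2, LAG3 was at 0.23, CD226 at 0.21 and NCR1 at −0.24. KLRC4 was 2.04 log2 units lower in pool 1 in 5 of 5 specimen labels run in another pool too.

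**Figure D1:**
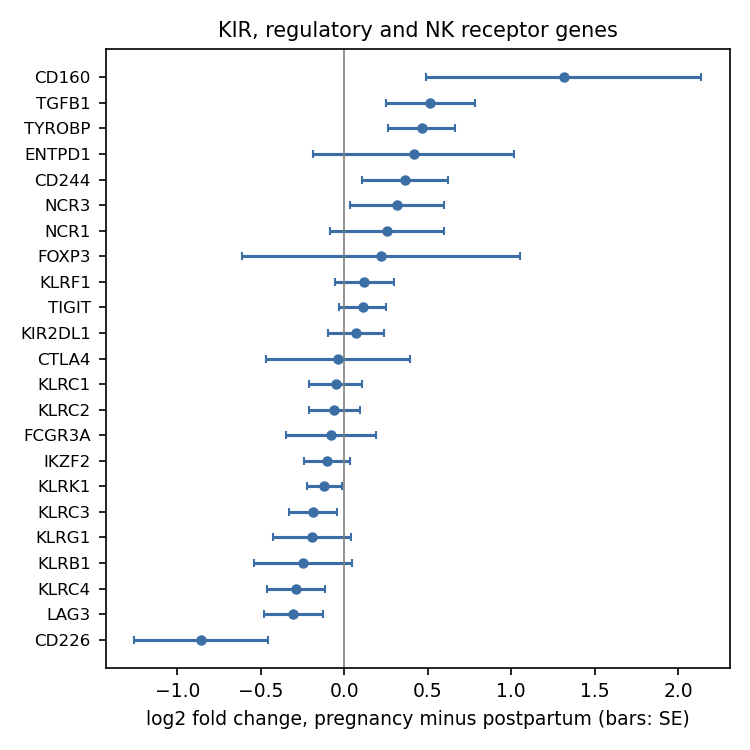
Log2 fold change, pregnancy minus postpartum, of the tested KIR, regulatory and NK receptor genes (x axis), 1 gene per line; points are fitted edgeR values with the donor as a block and bars are standard errors. No gene passed the threshold, and KIR2DL1 lies at 0.07 and IKZF2 at −0.11.

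The 6 genes with the smallest p did not pass. S100A4, a calcium-binding protein of memory and effector T cells, had 2.34 ± 0.54 (adjusted p = 0.387), but −0.057 without pool 1. In the 5 specimen labels run in both pool 1 and another pool, S100A4 was higher in pool 1 in 5 of 5, by 5.28 ± 0.67 log2 units (SD). IFIT3, an interferon-induced gene, had −0.86 ± 0.23 (lower in 5 of 6 paired donors), the chemokine gene CCL4 −1.29 ± 0.36, IGHM_membrane 1.95 ± 0.63, the chemokine gene CXCL1 2.76 ± 0.90 and RORA, a nuclear receptor, −0.38 ± 0.13. No list of 15 passed in limma's camera test (5 at an unadjusted p under 0.05, lowest adjusted p = 0.0812), but 3 passed with donor and pool as one block and 1 with the pool covariate in place of the donor block. The median log2 fold change was 0.29 for activation genes, −0.16 for homing, 0.36 for NK cell markers, 0.67 for B cell markers and 0.59 for myeloid markers, each with adjusted p = 0.0812. It was −0.18 for interferon response (8 of 8 members negative), −0.30 for cytokines and −0.11 for immediate early genes, each at adjusted p = 0.157, and −0.15 for cytokine receptors (adjusted p = 0.264). It was −0.09 for naive and memory genes, −0.11 for terminal effector, 0.20 for checkpoint, 0.02 for cytotoxic, 0.11 for regulatory and −0.06 for NK receptor genes, with adjusted p from 0.356 to 0.762; the camera direction of the NK receptor list was upward, against its median. Adjusted over the list alone, 1 gene passed in each of the interferon response, cytokine and B cell marker lists, against 0 over all genes tested.

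In the comparison of the third trimester with postpartum, IFIT3 fell to 0.416 of its postpartum level (log2 fold change −1.27 ± 0.22, adjusted p = 0.0186 in edgeR), from 744 ± 557 CPM postpartum (SD, n = 7) to 328 ± 309 (n = 12), and was lower in 5 of 5 paired donors. The call was lost with donor and pool as one block (−1.18 ± 0.21, adjusted p = 0.0536 in edgeR), with the pool covariate added to the donor block (−1.05 ± 0.26, adjusted p = 0.291) and with every cell thinned to 150 molecules (−1.21 ± 0.23, adjusted p = 0.0607). ISG15, a ubiquitin-like protein induced by type I interferon, had −0.52 ± 0.15 and was also lower in 5 of 5, without passing the threshold (adjusted p = 0.259). Among other interferon-induced genes, MX1 had −0.73 ± 0.29, OAS1 −0.68 ± 0.30, IFI6 −0.62 ± 0.33 and STAT1 −0.31 ± 0.20, while IFITM2 and IFITM3 both had −0.03. All 8 tested members of the interferon response list were negative, 1 passed over all genes and 2 adjusted over the list alone, and the list fell (median log2 fold change −0.57, adjusted p = 0.000379 in camera). With an estimated correlation between its genes, the list did not pass (adjusted p = 0.355), nor with fry (adjusted p = 0.198). The mean of the 8 genes differed by −0.62 ± 0.35 log2 units (SD), lower in the third trimester in 5 of 5 donors, and the exact two-sided sign-change test gave p = 0.0625, the smallest that 5 pairs allow. It was −0.28 ± 0.14 without pool 2 (3 of 3 donors lower) and −0.91 ± 0.16 without pool 3 (2 of 2 lower), and the list did not pass without pool 2 (median −0.26, adjusted p = 0.0655) or in one of the fits with a donor left out (adjusted p = 0.0515).

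**Figure D2:**
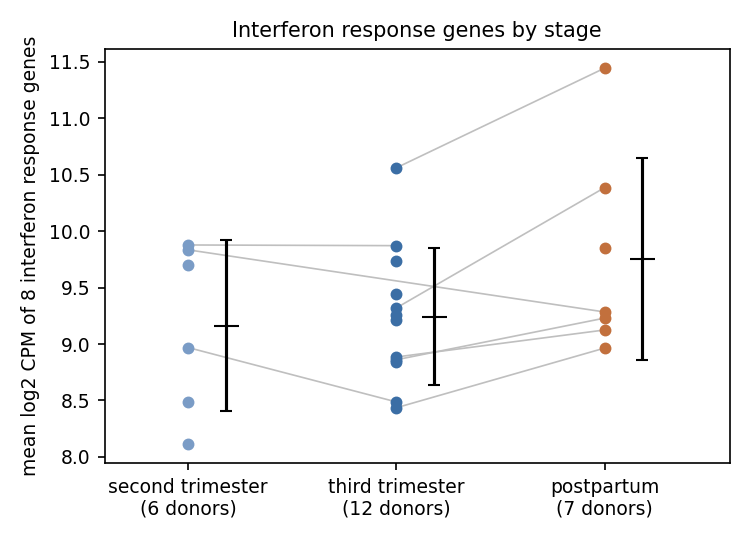
Mean log2 CPM of the 8 tested interferon response genes (y axis) by stage (x axis); each point is a donor, grey lines join the stages of a donor, and black bars give the mean and SD. In all 5 donors with both stages, the third trimester value lies below the postpartum value.

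The other called gene was CD14, with a log2 fold change of 3.31 ± 0.50 (adjusted p = 0.0134, higher in 5 of 5 paired donors), from 32.3 ± 32.6 CPM postpartum to 255 ± 409 in the third trimester. With the pool covariate added to the donor block, CD14 was at 3.65 ± 0.66 and did not pass (adjusted p = 0.0767 in edgeR). The myeloid marker list rose with it (3 members tested, median 1.64, adjusted p = 2.24e-05 in camera, adjusted p = 0.0696 with an estimated correlation). With any donor left out, fewer than 3 of its members were tested, so the list was not tested there. The inflammatory chemokine and cytokine genes CXCL1 (3.70 ± 0.85), CXCL2 (2.07 ± 0.60), CCL2 (3.07 ± 0.91) and IL1B (2.97 ± 0.83) and the lysosomal gene CD68 (0.65 ± 0.18) had the next smallest p and did not pass. With each donor left out, CXCL1 ran from 2.64 to 5.20, CXCL2 from 1.4985 to 2.55, CCL2 from 1.55 to 3.83 and IL1B from 2.23 to 3.83. In the third trimester, 89.4% of the 870 CD14 molecules lay in cells not annotated as CD8 T cells, and 89.9% in 10 cells. The share outside CD8-annotated cells was 93.2% for CXCL1, 93.3% for IL1B and 94.5% for CCL2, but 24.2% for CD68. It was 3.72% for IFIT3. Summed over CD8-annotated cells, CD14 had too few counts to be tested, CXCL1 had −0.13, CXCL2 −0.23 and CCL2 −0.61, and no gene passed in edgeR (13 at an unadjusted p under 0.05), with IFIT3 at −1.17 ± 0.21 (adjusted p = 0.0529). The count of 2 called genes fell to 0 or 1 with each donor left out, and IFIT3 then had adjusted p from 0.0849 to 0.226, at log2 fold changes from −1.33 to −1.08. With all donors and cells, 21 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 5.

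In the second trimester against postpartum, 1 donor had both sides, so the fit took the pool and not the donor as a covariate. The fit thus mostly compared different donors. Of the 8 tested interferon response genes, 6 had negative values in it, ISG15 −1.07 ± 0.33, IFI6 −1.26 ± 0.43, IFIT3 −1.74 ± 0.60, MX1 −1.27 ± 0.48, OAS1 −1.39 ± 0.54 and STAT1 −0.47 ± 0.30, while IFITM2 had 0.36 ± 0.23 and IFITM3 0.29 ± 0.34. The 1 donor with both sides went the other way for each of them. In that donor the same 6 genes were higher in the second trimester, IFIT3 only slightly, and IFITM2 and IFITM3 were lower. The cytotoxic granule gene GNLY had 1.44 ± 0.40 with 58247 ± 41121 CPM in the second trimester (SD, n = 6) against 37148 ± 15929 postpartum (n = 7), and the inhibitory NK receptor gene KLRC1 had 1.09 ± 0.37. None of the 319 genes passed (edgeR, 24 at an unadjusted p under 0.05, lowest adjusted p = 0.408). The interferon response list passed in camera (median −1.16, adjusted p = 0.0291), with 5 of its 8 genes past the threshold adjusted over the list alone and 0 over all genes; it did not pass with an estimated correlation (adjusted p = 0.667). S100A4 had 1.56 ± 0.50, but −0.000299 with donor and pool as one block. With the donor as a block in place of the pool, ISG15 had a value of the opposite sign (0.17), IFI6 was at −0.46 and IFIT3 at −0.45.

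Between the trimesters, KLRC1 had the smallest p. This gene, which encodes the inhibitory receptor NKG2A, was at 1809 ± 1011 CPM in the third trimester (SD, n = 12) and 3868 ± 1320 in the second (n = 6), a log2 fold change of −1.35 ± 0.31 that did not pass (adjusted p = 0.0601 in edgeR). KLRC2, encoding the activating receptor NKG2C, had −1.20 ± 0.35 (1809 ± 990 against 3766 ± 1463 CPM), and GNLY −1.07 ± 0.34. KLRC1 and KLRC2 had nearly equal CPM in both trimesters. Whether the panel tells their molecules apart was not tested, so they may not be separate changes. The fits covered the pool, since 2 donors had both trimesters, and the pool fits rest mostly on different donors. None of 319 genes passed (edgeR, 19 at an unadjusted p under 0.05), while DESeq2 called 3 and a single gene passed with the donor as a block. CXCL8 (2.98 ± 0.91), CXCL1 (3.41 ± 1.09) and IL1B (3.23 ± 1.08) also did not pass, and CXCL8 and IL1B had values of the opposite sign in CD8-annotated cells (−0.26 and −0.10). No list passed (NK receptor list, median −0.15, adjusted p = 0.213).

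A beta chain was found in 67.4% of cells, and 27 specimens had at least 30 such cells. In a draw of 30 cells, cells in clones of 2 or more made up 32.5% ± 24.6 in the second trimester (SD, n = 5 donors), 45.2% ± 23.2 in the third trimester (n = 10) and 41.6% ± 25.5 postpartum (n = 7). In the 5 donors with both sides, the share was 48.2% in pregnancy and 44.9% postpartum, a difference of 3.37 ± 6.96 percentage points (SD, higher in pregnancy in 3 of 5; from 1.24 to 5.56 with each donor left out), which the exact two-sided sign-change test did not separate from 0 (p = 0.375, smallest possible 0.0625). The largest clone held 21.8% of cells with a beta chain in pregnancy and 19.9% postpartum in the same donors, a difference of 1.97 ± 2.82 points (exact p = 0.25; from 1.16 to 2.85 with each donor left out). Between all donors, expansion was 1.20 points lower in pregnancy (permutation p = 0.917).

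**Figure D3:**
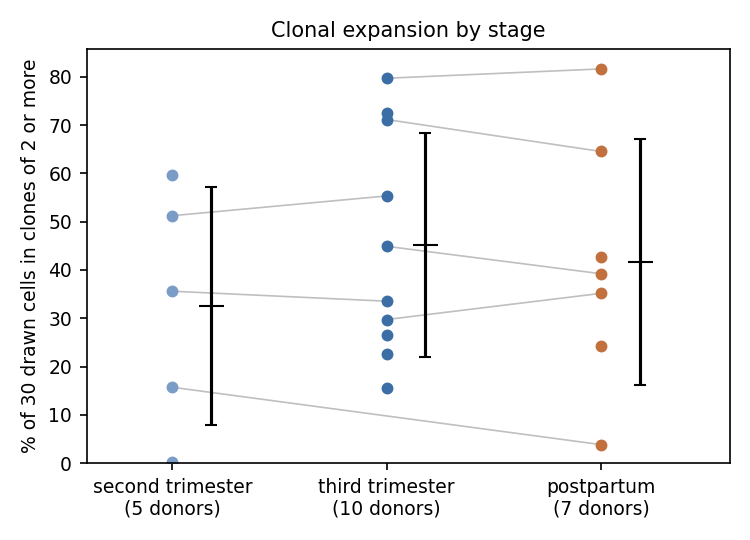
Percent of 30 drawn cells that fall in clones of 2 or more cells (y axis) by stage (x axis); each point is a donor, grey lines join the stages of a donor, and black bars give the mean and SD. The spread between donors (SD 23.2 to 25.5) exceeds the mean differences between stages.

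Clustering of all single-tag cells gave 7 clusters. Cluster 1 (4177 cells) was cytotoxic effector CD8-like, led by FCGR3A, FGFBP2, CX3CR1, GZMH and GZMB, and cluster 4 (1800 cells) was naive or central memory CD8-like, led by CCR7, SELL, LEF1 and CD27. Cluster 7 (167 cells) was MAIT-like, led by ZBTB16, CCR6, RORC and KLRB1. The other clusters had too few markers of a type and stayed unnamed: cluster 2 (3381 cells) was led by GZMK, CXCR6 and XCL2, cluster 3 (3335 cells) by VEGFA and glycolytic genes such as ENO1, cluster 5 (1708 cells) by CD4, ZNF683 and CD2, and cluster 6 (936 cells) by ZNF683, HAVCR2, KLRC2 and KLRC1. Cluster 3 drew 41.6% of its cells from a single specimen. In the 6 paired donors, the effector cluster was lower in pregnancy by 2.10 ± 5.98 percentage points (SD of the differences), the naive-like cluster by 1.23 ± 10.3 and the MAIT-like cluster by 0.760 ± 1.32, while cluster 2 was higher by 1.14 ± 9.32, cluster 3 by 2.61 ± 19.6 and cluster 6 by 0.979 ± 3.29, and cluster 5 was lower by 0.643 ± 8.40. No share passed (exact sign-change tests, adjusted p = 0.844 for all 7 clusters). With 6 pairs, the smallest unadjusted p that this test allows was 0.03125. After adjustment over 7 clusters, a change in a single cluster could therefore not pass, however even between donors. Over all donors, unpaired, cluster 1 was higher in pregnancy by 1.17 points, cluster 3 by 0.313, cluster 4 by 1.23, cluster 6 by 7.41 and cluster 7 by 0.789, while cluster 2 was lower by 1.16 and cluster 5 by 9.75, so clusters 1, 2, 4 and 7 had the opposite sign (permutation tests, adjusted p from 0.627 to 0.998).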

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

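Of the tests in this part, the one on the mix of cell states within cluster 1 was written before its result was seen, and the others were chosen after. In the second trimester, 1 of the donors had a share of cluster 1, the effector-like cluster, apart from the rest, with a gap of 0.700 of the group's range. Postpartum, 1 of the donors stood apart in the share of cluster 7, the MAIT-like cluster, with a gap of 0.658 of the range. Chance gives such a gap in about 1 of 20 groups, or 1.1 of the 22 groups tested. Cells annotated as NK cells made up 0.626% of all cells (97 cells), and a gamma chain was the dominant chain in 3.57% (553 cells).

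CD14 and other monocyte-type genes had higher values in the third trimester than postpartum. Whether the KIR+ CD8 T cells were the source could not be decided with the deposited annotation. In CD8-annotated cells, the median log2 fold change of CXCL1, CXCL2, IL1B, CCL2 and CD68 was −0.13 (median SE 0.40). IL1B was at 0.19 ± 0.35 there and CD68 at 0.10 ± 0.24. The caller of cell types is not given, and a caller that used expression would itself remove cells high in these genes. For CD68, moreover, only 24.2% of the third trimester molecules lay outside those cells. A few monocytes in the sorted cells are a candidate explanation. By the same annotation, 89.4% of the CD14 molecules of the third trimester lay in cells not called CD8 T cells. The deposited annotation counted 10 classical monocytes, with a median of 3860.5 molecules per cell and 100% of them without an alpha or beta chain. Their share was 0.405% in pregnancy and 0.0556% postpartum in the 6 donors with both, higher in 4, and an exact two-sided sign-change test did not separate the difference from 0 (p = 0.125).

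S100A4 had a higher value in pregnancy than postpartum, without passing the threshold. A biological difference between pregnancy and postpartum is argued against by the log2 fold change without pool 1, which was −0.057. A difference between pools may account for the pattern, since S100A4 was 5.28 log2 units higher in pool 1 than in the other pool for specimens with the same label, the largest such difference of the 319 genes. Pool 1 held pregnancy specimens only. What made pool 1 differ was not tested.

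The interferon response list was lower in the third trimester than postpartum. A difference between pools, other cell types in the sort and the depth per cell are each argued against as the whole cause of the lower list median. It was −0.57 in the main fit, −0.52 with donor and pool together as the block, −0.49 in CD8-annotated cells and −0.69 with every cell thinned to 150 molecules. The list passed in camera each time at the preset correlation, but an estimated correlation was not run with these settings. The argument thus rests on the medians and not on these calls. All 8 members were lower in pool 1 than in the other pool for specimens with the same label, from −0.089 for MX1 to −1.11 for IFI6, but without pool 1 the list median was −0.48; in the fit of all cells the list did not pass with an estimated correlation (adjusted p = 0.355 in camera), and without pool 2 it did not pass either (median −0.26, adjusted p = 0.0655), with the mean over donors at −0.28 in place of −0.62. Changed shares of the clusters alone would leave no difference within clusters. The mean difference was −0.45 in cluster 1 (SD 1.09, lower in 3 of 4 donors), −0.70 in cluster 2 (SD 0.28, 4 of 4), −0.57 in cluster 3 (SD 0.40, 3 of 3), −0.10 in cluster 4 (SD 0.43, 2 of 3) and −0.93 in cluster 5 (SD 0.63, 4 of 4). With the clusters weighed equally it was −0.65 ± 0.23 (SE), lower in 4 of 5 donors (exact two-sided sign-change test, p = 0.125, smallest possible 0.0625). These means are all negative, but with so few donors and this spread a changed mix of cell states stays undecided. An effect of the stage of pregnancy may account for it and stays open, since 5 pairs allow no exact p under 0.0625, the value found. With both trimesters taken as pregnancy, 6 donors were paired, and the mean difference was −0.42 ± 0.57 (SD), lower in 5. The exact two-sided sign-change test then gave p = 0.156, where 0.03125 was the smallest possible. An interferon response after delivery, such as to an infection, was not tested.

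Other splits of the specimens were fitted in the same way. For the third trimester against postpartum, 1 of 32 splits gave as many called genes, the real one (2 genes, highest other 1). This margin of 1 gene is too small to exclude chance, and the count fell to 0 or 1 with each donor left out. Chance cannot be excluded for the lists of this comparison either, where 13 of 32 splits gave as many (real 2, highest other 5). Where the real count was 0, every split gives as many, so the count of splits tells nothing about chance. This holds for pregnancy against postpartum in genes (64 of 64, highest other 1) and lists (64 of 64, highest other 6), for the second trimester against postpartum (100 of 100, highest other 1) and between the trimesters (100 of 100, highest other 7). The splits with 6 lists or 7 genes may point to a structure of the specimens other than their stage, which was not tested.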

How the results depend on the processing

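Of 1313 alternative values for 55 named genes and lists, 1209 counted as unchanged, 24 no longer passed, 29 newly passed and 51 counted as changed in direction. The 1209 kept their side of the threshold. They include values of genes that did not pass and changed sign by no more than 1 SE. For a comparison's main value or count, 145 alternatives stayed close, 43 moved and 3 changed direction. The cause was not tested unless named. The settings with CD8-annotated cells, thinned cells, donor and pool as one block, and the list alternatives for the third trimester were chosen after seeing the data. IFIT3 in the third trimester ranged from −1.56 to −1.05, with adjusted p from 0.000591 to 1.00. Pool 1 alone could not be fitted against postpartum, as it held no postpartum specimen. No cluster share passed under any of 6 alternatives. Without pool 2 or without pool 3 none could pass, since 3 donors were paired and the sign-change test allowed no p under 0.25.

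For pregnancy against postpartum, with the pool as covariate and no donor block, CTLA4 was at 0.90, IKZF2 at 0.16, TGFB1 at −0.10, CD160 at −0.35, KLRC1 at 0.42, KLRC2 at 0.39, KLRC3 at 0.29, KLRC4 at 0.041 and KLRF1 at −0.27, and 1 list passed. With both the donor block and the pool covariate, ENTPD1 was at −0.68, IKZF2 at 0.11 and TGFB1 at −0.10. With donor and pool as one block, S100A4 was at −0.065, IKZF2 at 0.036, TGFB1 at −0.032 and KLRC3 at 0.048, and 3 lists passed. Without pool 1, S100A4 was at −0.057, IKZF2 at 0.077 and KLRC3 at 0.089. Without pool 2, LAG3 was at 0.23, CD226 at 0.21, NCR1 at −0.24 and the NK marker list at 0.040 (its camera direction was downward), and 1 list passed; in pool 2 alone, CTLA4 was at 0.82, IKZF2 at 0.10, TGFB1 at −0.15, FCGR3A at 0.53 and KLRC3 at 0.13. Without pool 3, CTLA4 was at 0.65 and FCGR3A at 0.49; in pool 3 alone, S100A4 was at −0.41, LAG3 at 0.20, CD226 at 0.092 and NCR1 at −0.31. In cells with an alpha or beta chain KLRC2 was at 0.10, in thinned cells KIR2DL1 was at −0.11 and 1 gene passed, and with the trimesters merged KLRB1 was at 0.090. DESeq2 called 4 genes. With each donor left out, 0 to 2 genes and 0 to 2 lists passed, and KIR2DL1 ran from −0.13 to 0.22, KLRF1 from −0.096 to 0.25 and NCR1 from −0.088 to 0.37.

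For the third trimester against postpartum, 0 genes passed without pool 2, in pool 2 alone, without pool 3, in pool 3 alone, with donor and pool as one block, in CD8-annotated cells, in thinned cells and without cells over 3 times the median. The count was 1 with the donor block and pool covariate, a gene other than IFIT3 and CD14, which both did not pass there. It was 1 in cells with an alpha or beta chain (IFIT3), 5 in DESeq2, and 0 to 1 with each donor left out. CCL2 was at −0.66 in cells with a chain, −0.62 without cells over 3 times the median and −0.61 in CD8-annotated cells, where CXCL1 was at −0.13 and CXCL2 at −0.23. Of its lists, 0 passed with an estimated correlation, and 1 passed with fry, without pool 2, in CD8-annotated cells, with donor and pool as one block and with any donor left out (1 to 1). It was not always the same list. With fry it was the myeloid marker list (adjusted p = 0.0249). Without pool 2 and in one of the fits with a donor left out, it was a list other than interferon response. In the rest of these settings it was the interferon response list.

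For the second trimester against postpartum, 1 gene passed with no filter, 1 with at least 50 cells per specimen, and 0 to 1 with each donor left out. ISG15 was at 0.17 with the donor block and 0.24 with donor and pool as one block, where S100A4 was at −0.000299. Between the trimesters, 1 gene passed with the donor block, 3 in DESeq2, 2 with no filter, 1 in cells with a chain and 0 to 1 with each donor left out. CXCL8 was at −0.32 in cells with a chain and −0.26 in CD8-annotated cells, where IL1B was at −0.10. Clonal expansion was −1.20 points over all donors, unpaired. The difference in cells without a chain was −2.43 points without pool 3, and from −1.42 to 4.42 points with each donor left out.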

Other observations

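The contrast between expanded and single-cell clones, the persistence of clones and their tests were all added after the data were seen. Cells of expanded clones (3 or more cells, 7679 cells) were compared with cells of single-cell clones (1871 cells) in 18 donor-by-stage units from 12 donors, so that some donors entered more than once. In edgeR, 102 of 245 tested genes passed, 57 higher and 45 lower in expanded clones. Genes of naive and central memory T cells fell, with CCR7, a lymph node homing receptor, at a log2 fold change of −3.61, LTB at −2.64, LEF1 at −2.38, SELL at −2.24, CD27 at −2.21 and CD28 at −2.16. The naive and memory list fell (10 of 11 members lower, median −2.21, adjusted p = 1.62e-09 in camera, adjusted p = 0.0155 with an estimated correlation). Cytotoxic genes rose, with GZMB at 1.33, GZMH at 1.27 and PRF1 at 0.93, and 10 of the 12 members passed upward and 1 downward (list adjusted p = 0.000174, adjusted p = 0.149 with an estimated correlation). The terminal effector list rose with 7 of 8 members (adjusted p = 0.000431, adjusted p = 0.158 with an estimated correlation), among them ADGRG1 (1.08), CX3CR1 (0.94) and FCRL6 (0.88). The interferon response list did not pass (median −0.06, adjusted p = 0.670).

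DESeq2 called 111 genes in this contrast, a fit with no filter 112 and a fit with library sizes alone 122, of which 41 were higher and 81 lower. Of 100 splits with the classes exchanged within units, 1 gave as many genes, the real one (102, highest other 54). No other exchange of the classes thus reached the real count. Units of the same donor were exchanged separately, though they are not independent, and the splits do not exclude chance for any single gene.

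Clones of pregnancy were sought in the postpartum cells of the same donor. The control was the share of postpartum cells whose clone was present in the pregnancy cells of any other donor, a sequence match that wrongly assigned tags would give. By mere presence, 63.9% ± 33.9 of postpartum cells (SD, n = 5 donors) matched within donors, against 49.0% of 3646 cells in the control, so this measure could not be used. In clones of 10 or more cells, 0.219% of cells in pool 1, 1.05% in pool 2 and 1.36% in pool 3 carried the tag of a donor other than that of most of the clone. Then 105 of the 10450 cells with a beta chain, counted as wrongly assigned, were dropped, a filter that by its making lowers the control. These 105 cells were not limited to the clones of 10 or more cells. The share within donors was then 63.9% ± 34.8 at 1 cell or more on the other side (control 9.72% of 3601 cells), 60.2% ± 35.5 at 2 or more (control 0 of 3601) and 58.3% at 3 or more (control 0 of 3601). Without the filter, the shares were 60.2% at 2 or more (control 34.01%) and 57.6% at 3 or more (control 32.9%). The filter and the cell minimum were chosen after the high control was seen.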
